A study of Drosophila melanogaster with 4 samples.

How the data were processed

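Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map HP2 in nuclei of wild-type Oregon-R Drosophila melanogaster at the third larval instar. HP2, the product of Su(var)2-HP2, is a chromatin protein that binds the heterochromatin protein HP1a. The antibody is named Ab2-90 in the labels. The series holds 4 libraries, 2 ChIP libraries and 2 input libraries, numbered as replicates 1 and 2. Per the labels, each input was used as the input for the cluster list of the ChIP library of the same number. Per the labels' protocols, larval tissue was homogenised and fixed with formaldehyde, nuclei were lysed with SDS, chromatin was sheared by sonication, and precipitation used protein A beads. Whether the replicates came from separate collections of larvae is not given in the sources used here, so the spread between them may be technical.

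Reads were aligned with Bowtie version 0.12.7, per the submitters' processing notes. The processed data are 3 lists of significantly enriched regions in GFF3 format, here called clusters. There is 1 list for each ChIP replicate and 1 list for the replicate set as a whole, here called the combined list. Each cluster has a start, an end and a score deposited by the authors. The scale of this score, the region caller, its threshold and the way the replicates were combined are not given in the sources used here. The score was therefore used only to rank clusters and to compare groups of clusters within a list. Differences between the lists in the size of the score are not interpreted. Coordinates are on FlyBase release 5, per the file headers, and are given 1-based. The headers also give the lengths of all chromosomes. The 29.0 Mb of Uextra, on which no list has a cluster, was left out of all shares of sequence. In the combined list 1 cluster started below position 1, and 2 clusters in the combined list and 2 in the replicate 2 list ended past the stated length of their chromosome. These were trimmed to the chromosome.

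The lists hold no read counts, so the depth of the libraries is unknown and no value could be weighted by it. The inputs enter only through the authors' calls. The precision of a share of clusters is given as an exact (Clopper-Pearson) 95% binomial interval. These intervals cover counting error only, and neighbouring clusters are not independent of each other. Means are given with the SD over the 2 ChIP replicates, and no test across replicates was run, because with 2 libraries an exact two-sided sign-flip test cannot give a p under 0.5.

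Clusters were assigned by their midpoint to 5 classes. These were chromosome 4, the 6 named heterochromatin scaffolds (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet), the unplaced sequence U, the centromere-proximal 1 Mb of each of the 5 arms 2L, 2R, 3L, 3R and X, and the rest of those arms. Cover is the percentage of a sequence that lies under clusters. Clusters of the replicates were counted as overlapping when they shared at least 1 bp. The overlap was set against 1000 random circular shifts of the replicate 2 clusters within each chromosome, with a one-sided p that cannot go below 0.001. For the shares of replicate 2 clusters by class, the replicate 1 clusters were shifted instead. Cover in 100 kb windows was compared by Spearman correlation against 1000 rotations of the windows within each chromosome. Scores of overlapping pairs were compared by Spearman correlation, and median scores of classes by their difference, each with a two-sided permutation p from 100000 resamples that cannot go below 1e-05. Intervals of median differences come from 2000 bootstrap resamples of clusters. The overlap procedure was run on simulated data with the 4092 replicate 1 clusters, where planted overlaps of 20.0%, 50.0% and 80.0% were returned as 20.0%, 50.0% and 80.0%. The planted clusters were exact copies and all other simulated clusters avoided replicate 1, so this return was fixed by construction and checks only the counting. Of 20 unrelated simulated lists, 0 reached a p under 0.05. Their clusters were placed evenly at random, and were fewer and narrower than those of replicate 2. False positives between lists with clustered regions were therefore not checked.

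The designs, the classes and most alternatives were fixed before the data were examined. The alternatives were the higher-scoring 50% of each list, clusters merged within 1 kb, stricter and looser overlap rules, lists of equal length, a proximal window of 2 Mb, windows of 50 and 200 kb, and leaving out each replicate. The clusters named in the text are the 10 highest-scoring combined clusters that overlap a cluster in both replicates and the 2 highest such clusters on each of 2L, 2R, 3L, 3R, X and 4. The windows named are the 10 with the highest mean cover. Added after seeing the data were the extent of the pericentric blocks, each arm's proximal window by itself, the overlap in the rest of the arms alone, the overlap of each class against its own shifted value, the score differences within 10 bins of cluster width, the correlation of cover outside the proximal 2 Mb, the scores of clusters found in both lists, and the comparison of scores between the heterochromatin scaffolds and chromosome 4. The 7 gene lists fixed in advance were not tested, and no cluster was assigned to a gene, because the gene table at hand is on release 6 and coordinates were not converted between releases. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.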

Results

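The distribution of HP2 was mapped in 2 ChIP-seq libraries from nuclei of wild-type larvae, each called against its own input. The list of replicate 1 held 4092 enriched clusters that covered 10.0 Mb, or 7.17% of the assembled sequence without Uextra. Replicate 2 gave 7017 clusters covering 21.6 Mb, or 15.4%. The mean was 5554.5 ± 2068 clusters (SD, n = 2), and the replicate 2 list was 1.71 times as long and covered 2.15 times as much sequence. Median cluster widths were 1.97 kb and 2.07 kb. Median scores were 0.573 and 0.632 within the respective lists, in the authors' units. The depth of the libraries is unknown. The combined list held 12660 clusters covering 32.5 Mb.

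HP2 clusters were concentrated on chromosome 4, on the heterochromatin scaffolds of chromosomes 2 and 3 and in the centromere-proximal parts of arms 2L, 2R and 3L. Chromosome 4, the small and largely heterochromatic autosome that nevertheless carries active genes, was the most densely covered of the 5 classes, with 39.3% of its 1.35 Mb under clusters in replicate 1 and 64.3% in replicate 2. The heterochromatin scaffolds, which hold repeat-rich sequence assigned to a chromosome but not joined to its arm, were covered to 19.0% and 50.1%. YHet, at 0.818% and 8.95%, lay below the rest of the arms in both replicates, and XHet, at 2.99% and 28.2%, in replicate 1. These values rest on 2 and 15 clusters on YHet and 4 and 18 on XHet. The lists do not show how much of each sequence could be mapped and called. Low cover of a scaffold therefore does not by itself show a lack of HP2, and differences in cover between classes need not equal differences in binding. The proximal 1 Mb windows of the 5 arms together were covered to 27.5% and 49.5%. The rest of the arms, which is mostly euchromatin, was covered to 5.16% and 10.1%. The cover thus differed between the replicates by about as much as it differed between some classes, so the classes were compared within each replicate.

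Relative to the rest of the arms, the cover of chromosome 4 was 7.01 ± 0.87-fold higher (SD, n = 2). It was 5.12 ± 0.30-fold higher in the proximal windows and 4.33 ± 0.93-fold higher on the heterochromatin scaffolds. All 3 folds exceeded the spread between replicates. The unplaced sequence U did not separate from the arms, at 0.89-fold in replicate 1 and 2.08-fold in replicate 2.

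Counted by number, chromosome 4 held 147 clusters, or 3.59% (95% interval 3.04 to 4.21%), in replicate 1 and 151 clusters, or 2.15% (1.83 to 2.52%), in replicate 2. It makes up 0.97% of the sequence. The heterochromatin scaffolds, 6.64% of the sequence, held 14.9% (13.8 to 16.0%) and 13.6% (12.8 to 14.5%) of the clusters. The proximal windows, 3.58% of the sequence, held 9.53% (8.65 to 10.5%) and 5.73% (5.20 to 6.30%). The rest of the arms held 66.8% and 67.8% of the clusters on 81.6% of the sequence. Chromosome 4 carried almost the same number of clusters in both lists, and its larger cover in replicate 2 went with wider clusters, with a median of 2.77 kb against 2.37 kb.

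**Figure D1:**
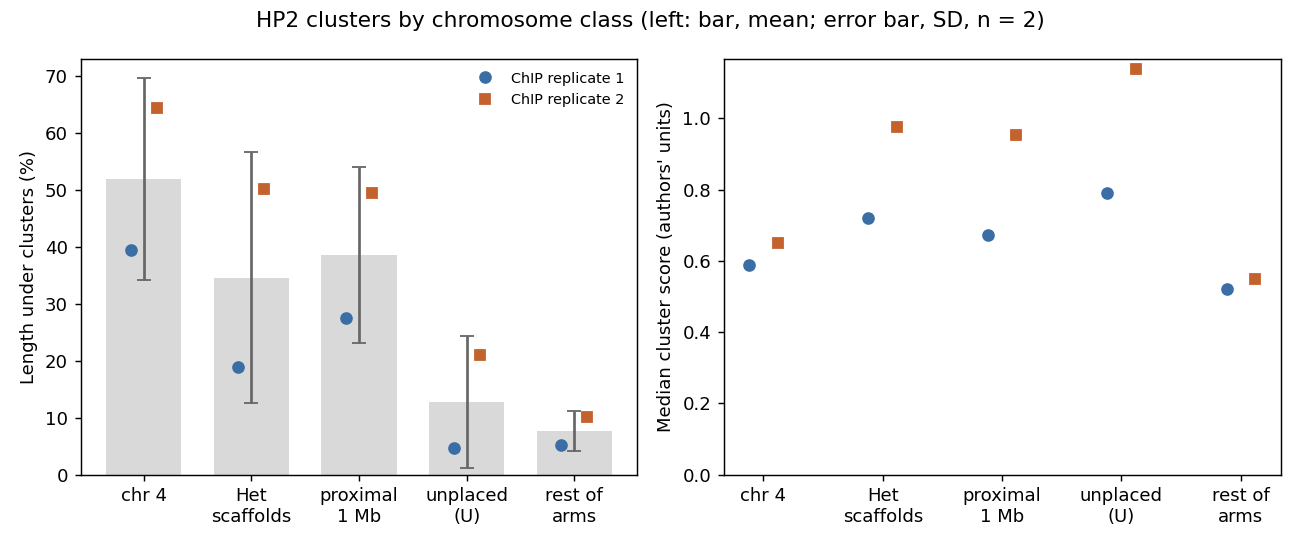
Percentage of sequence under HP2 clusters (left) and median cluster score in the authors' units (right) for 5 chromosome classes. Circles are ChIP replicate 1 and squares are ChIP replicate 2, with bars for the mean and error bars for the SD (n = 2) on the left. Chromosome 4 has the highest cover (39.3% and 64.3%) but a median score of only 0.587 and 0.651, below the heterochromatin scaffolds in both replicates.

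The proximal enrichment differed from arm to arm. On 2R the proximal 1 Mb was covered to 59.8% in replicate 1 and 81.7% in replicate 2, which is 7.91-fold and 5.99-fold the cover of the rest of that arm. On 2L the cover was 38.9% and 68.6% (8.90-fold and 8.31-fold), and on 3L it was 29.5% and 68.5% (5.51-fold and 7.07-fold). The densely covered blocks delimited below extend to 1.6 Mb on 2R and 1.5 Mb on 3L, but only to 0.9 Mb on 2L. The rest of 2R and of 3L thus includes part of their blocks, which lowers their folds, so the arms cannot be ranked by fold. On 3R the proximal 1 Mb was covered to only 6.18% and 15.6% (1.34-fold and 1.95-fold). On the X it was covered to 3.26% and 12.9%, which was 0.78-fold and 1.12-fold of the rest of the X, so no proximal enrichment was detected on the assembled X arm. These windows are counted from the end of each assembled arm and leave out sequence not joined to it. The scaffold 3RHet was covered to 14.3% and 44.3%, and XHet to 2.99% and 28.2%. The contrast between arms therefore holds for the assembled arms only.

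The proximal blocks were delimited by cover. Counting 100 kb windows from the proximal end until the mean cover fell under 25%, the block on 2R ran from position 1 to 1600000, the block on 2L from 22111545 to 23011544 and the block on 3L from 23043558 to 24543557. The 2R block was covered to 60.1% and 82.9% in replicates 1 and 2, its last window to 47.7% and 78.8%, and the 500 kb beyond it to 4.15% and 10.9%. The 2L block was covered to 43.0% and 75.4%, its last window to 37.6% and 67.3%, and the 500 kb beyond it to 3.06% and 7.47%. The 3L block was covered to 33.8% and 70.1%, its last window to 52.5% and 81.4%, and the 500 kb beyond it to 3.13% and 14.6%. On 3L in replicate 2 the cover beyond the block was thus still above the 9.69% of the arm outside its proximal window. The rule places the last window at or above a mean cover of 25% and the next window under it. A drop at the border therefore follows in part from the rule and is no separate result. On 3R only the first 100 kb passed, and on the X no window did. The 2R block kept its extent of 1.6 Mb in either replicate alone. Without replicate 2 the 2L block shortened from 0.9 to 0.6 Mb, the 3L block from 1.5 to 0.1 Mb and the 3R block from 0.1 to 0 Mb. At a limit of 40% the 3L block also shortened to 0.1 Mb and the 3R block to 0 Mb.

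Windows along the chromosomes ranked alike by cover in the replicates, although the level of cover differed. The cover of whole chromosomes and scaffolds in replicate 2 was from 1.64 times (chromosome 4) to 10.9 times (YHet) that in replicate 1. Over 1405 windows of 100 kb, Spearman's rho was 0.83, against a mean of 0.14 and a highest value of 0.34 in 1000 rotations (one-sided permutation p = 0.001, the smallest they can give). Windows are not independent replicates. In the 1091 windows of the arms outside the proximal 2 Mb, rho was 0.84 (rotated mean 0.02, one-sided permutation p = 0.001). Of the 10 windows with the highest mean cover, 7 lay on 2R between positions 400001 and 1500000, 2 on 3RHet between 1800001 and 2000000, and 1 on 2RHet at 400001 to 500000. Their cover ranged from 52.9% to 79.8% in replicate 1 and from 81.1% to 97.6% in replicate 2. The top window, 2R 400001 to 500000, was covered to 79.8% and 95.6%. All 14 windows of chromosome 4 were occupied, with a cover of 14.4% to 53.9% in replicate 1 and 44.9% to 82.9% in replicate 2.

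**Figure D2:**
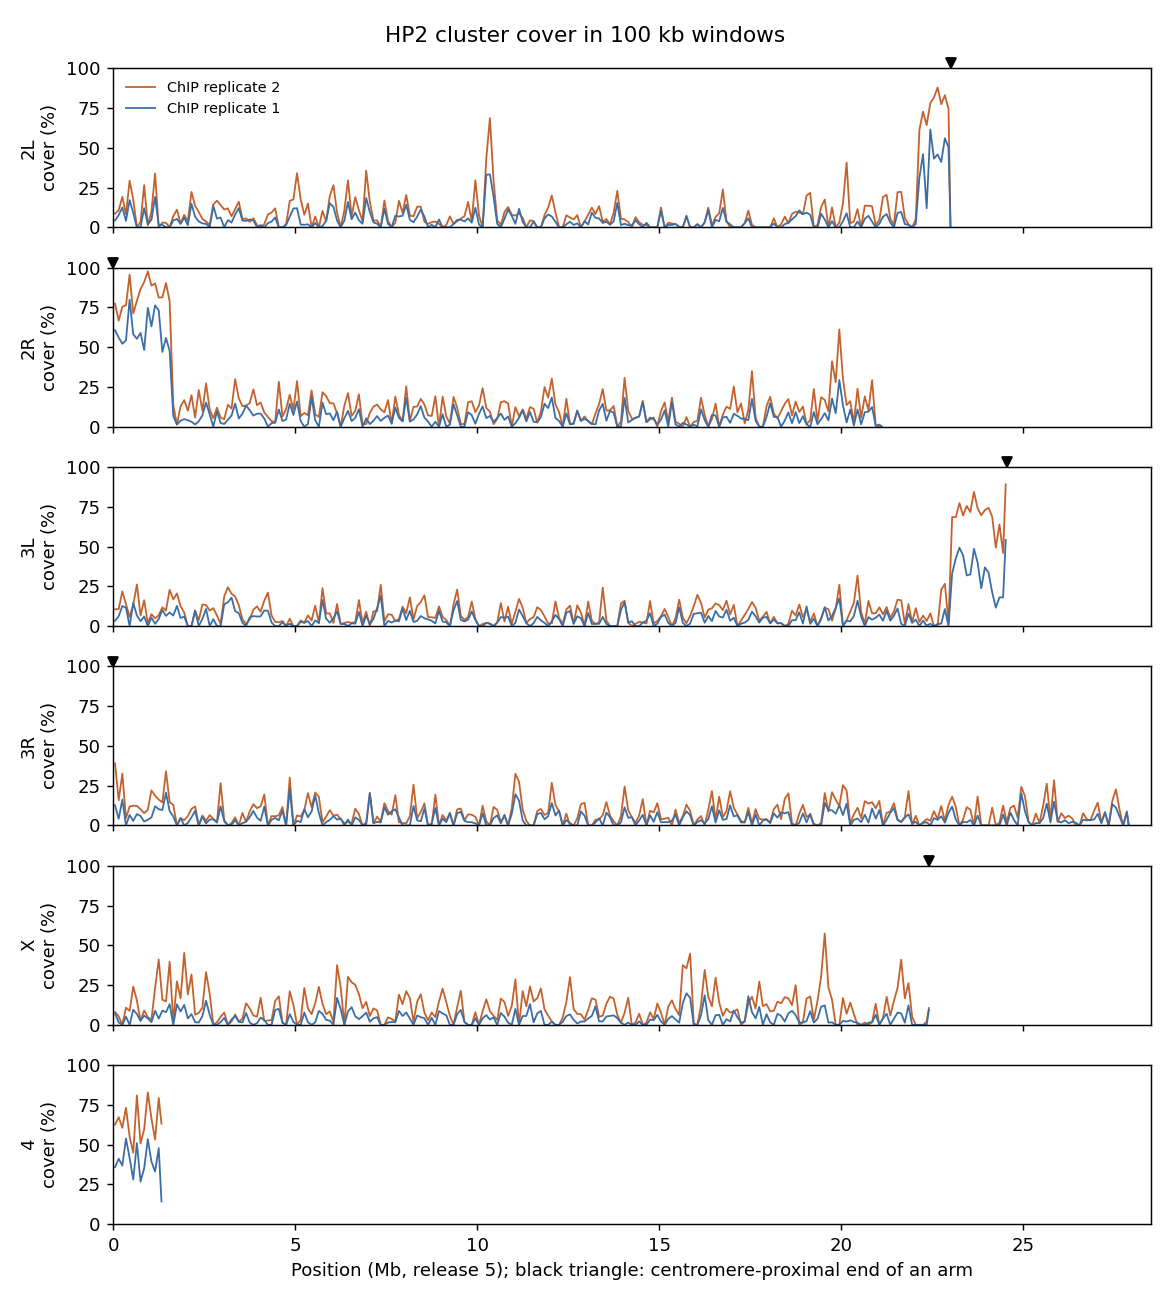
Percentage of each 100 kb window under HP2 clusters along the 5 arms and chromosome 4 (release 5 positions in Mb), with a line for each ChIP replicate. Black triangles mark the centromere-proximal end of each arm, where cover rises steeply on 2L, 2R and 3L (cover in the blocks 33.8% to 60.1% in replicate 1), while 3R and X lack a block of that extent, and each of the 14 windows of chromosome 4 holds clusters.

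Cluster scores were also higher on chromosome 4 and the heterochromatin scaffolds than in the rest of the arms, and the highest class median was that of unplaced sequence, at 0.790 in replicate 1 and 1.14 in replicate 2. In replicate 1 the median score was 0.704 for the 756 clusters on chromosome 4 and the heterochromatin scaffolds and 0.522 for the 2735 clusters in the rest of the arms, a difference of 0.183 (95% bootstrap interval 0.169 to 0.197, two-sided permutation p = 1e-05). In replicate 2 the medians were 0.951 and 0.548, a difference of 0.403 (0.374 to 0.437, permutation p = 1e-05). These p-values are the smallest that 100000 resamples can give. Clusters are not independent replicates, and neighbouring clusters may resemble each other. The p-values and intervals of the score differences here may therefore be too small and too narrow, and they do not measure the spread between libraries. The sizes of the 2 differences cannot be set against each other, since the scale of the score is not stated. Scores rose with cluster width (Spearman's rho 0.54 and 0.61), and within 10 bins of width the differences were 0.130 (0.113 to 0.145) in replicate 1 and 0.159 (0.134 to 0.195) in replicate 2, each with permutation p = 1e-05. Chromosome 4 taken by itself stood above the arms by 0.0652 (0.0206 to 0.103) in replicate 1 and by 0.103 (0.0467 to 0.208) in replicate 2, each with permutation p = 1e-05. The matching by width was run only on chromosome 4 and the scaffolds together. Chromosome 4 clusters were wider than those in the rest of the arms. Their median widths were 2.37 kb against 1.93 kb in replicate 1 and 2.77 kb against 1.99 kb in replicate 2. How much of the chromosome 4 difference goes with width is therefore unknown. Chromosome 4 lay below the heterochromatin scaffolds by 0.134 (0.0944 to 0.182) in replicate 1 and by 0.326 (0.208 to 0.384) in replicate 2, a comparison added after seeing the data (permutation p = 1e-05 in each). Chromosome 4 was thus the class with the highest cover but not the highest scores. Among the higher-scoring 50% of each list, the difference between heterochromatin and arms narrowed to 0.0430 in replicate 1 (permutation p = 5e-05) and 0.186 in replicate 2 (permutation p = 1e-05). This cut is made on the compared score itself, so a narrowing follows from the selection and is no separate result.

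The replicate lists overlapped far more than shifted lists. Of the 4092 replicate 1 clusters, 3519 or 86.0% (95% interval 84.9 to 87.0%) were overlapped by a replicate 2 cluster, against 30.7% on average in 1000 shifts and 35.6% at most (one-sided permutation p = 0.001). Of the 7017 replicate 2 clusters, 2923 or 41.7% (40.5 to 42.8%) were overlapped by a replicate 1 cluster, against 16.7% in shifted lists (permutation p = 0.001). The Jaccard index of the covered sequence was 0.38, against 0.08 in shifted lists. On chromosome 4, 145 of 147 replicate 1 clusters (98.6%) recurred in replicate 2, where shifted lists gave 82.2% (permutation p = 0.004). On the heterochromatin scaffolds 607 of 609 recurred (99.7%, shifted 69.7%), and in the rest of the arms 2185 of 2735 (79.9%, shifted 19.9%), each with permutation p = 0.001. In the other direction 42.0% of replicate 2 clusters on the scaffolds were overlapped (shifted 39.1%, permutation p = 0.021) and 43.3% in the rest of the arms (shifted 11.7%, permutation p = 0.001). On chromosome 4 it was 51.0%, below the 61.2% of shifted lists (one-sided permutation p = 0.999), so there the overlap lay above shifted lists in 1 direction only. The 145 overlapped replicate 1 clusters there fell on 77 of 151 replicate 2 clusters, so some replicate 2 clusters held more than 1 of them. The lower share therefore does not by itself show poorer agreement on chromosome 4. Arm clusters alone, trimmed to the arms outside the proximal windows, were overlapped in 79.9% of replicate 1 clusters against 17.9% in shifts kept to that part of the arms (permutation p = 0.001). Where a reciprocal overlap of at least 50% was required, the shares fell to 51.0% of replicate 1 and 29.7% of replicate 2, against 7.71% and 4.50% in shifted lists (permutation p = 0.001 for each).

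Clusters found in both lists had higher scores than the others and were wider, with medians of 2.04 kb against 1.48 kb in replicate 1 and 2.85 kb against 1.78 kb in replicate 2. In replicate 1 the median was 0.602 for overlapped and 0.483 for other clusters, a difference of 0.119 (0.107 to 0.131, permutation p = 1e-05), and in replicate 2 it was 0.849 against 0.555, a difference of 0.295 (0.274 to 0.323, permutation p = 1e-05). Within 10 bins of cluster width the differences fell to 0.0431 (0.0152 to 0.0567), from the 7 bins with enough clusters, and 0.0489 (0.0354 to 0.0664). The sign was not the same in all bins, with a lowest value of -0.00963 in replicate 1 and -0.0684 in replicate 2. Chromosome class was not matched. In replicate 1, 99.7% of scaffold clusters were overlapped against 79.9% in the lower-scoring rest of the arms, so part of the difference may go with class. Overlapped clusters in the rest of the arms had medians of 0.540 and 0.701 in replicates 1 and 2. All clusters there, overlapped ones included, had 0.522 and 0.548. Across the 3519 overlapping pairs the scores of the replicates were correlated, with Spearman's rho of 0.73 (permutation p = 1e-05). Clusters are not independent replicates.

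**Figure D3:**
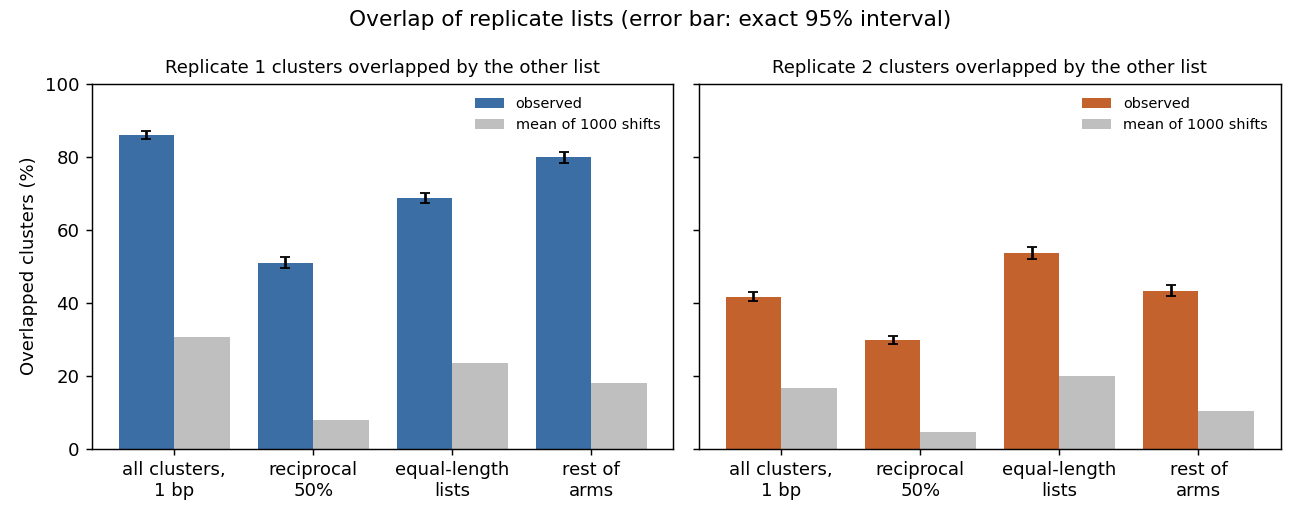
Percentage of replicate 1 clusters (left) and replicate 2 clusters (right) overlapped by the other list, under 4 settings. Coloured bars are observed values with exact 95% binomial intervals, and grey bars are means of 1000 circular shifts. Under each setting the observed share lies above the shifted mean, 86.0% against 30.7% for all replicate 1 clusters at 1 bp.

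The combined list went well beyond the replicate lists. It recovered 99.0% of replicate 1 clusters and 98.3% of replicate 2 clusters. Of its 12660 clusters, 2828 or 22.3% (21.6 to 23.1%) overlapped clusters in both replicates, 3785 or 29.9% only in replicate 2, 484 or 3.82% only in replicate 1, and 5563 or 43.9% (43.1 to 44.8%) in neither. Combined clusters seen in both replicates had a median width of 3.71 kb and a median score of 0.645, against 1.22 kb and 0.362 for those seen in neither. The share seen in both replicates was 42.3% of 175 combined clusters on chromosome 4, 41.7% of 487 in the proximal windows, 34.3% of 1102 on the heterochromatin scaffolds, 20.6% of 9709 in the rest of the arms and 14.5% of 1187 on unplaced sequence. These shares were not set against shifted lists, and overlap by chance is higher where cover is higher, so the classes cannot be ranked by them.

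Among combined clusters present in both replicates, 5 of the 10 highest-scoring lay on unplaced sequence, 2 on the X, and 1 each on 2L, 3R and 2RHet. The clusters on unplaced sequence had combined scores of 2.06 to 2.54, and 2 of them, the highest included, had a score shared with other combined clusters. The highest on a placed chromosome was at 2L 22787420 to 22789744, in the proximal window, with scores of 2.504 in the combined list, 2.74 in replicate 1 and 2.09 in replicate 2. It was followed by X 12475458 to 12478508 in the body of the X (2.42, 2.03 and 2.85) and 2RHet 469870 to 476806 (2.28, 1.80 and 1.59). The top cluster on 3R lay 56380 to 61206 from the proximal end (2.22, 1.83 and 2.72). The second X cluster was at 1972260 to 1975870 (2.04, 1.90 and 2.66). On 2R both leading clusters were proximal and wide, at 402374 to 434752 (32.4 kb, combined score 1.98) and 356552 to 371490 (14.9 kb, 1.96). On 3L the leading cluster was at 6971718 to 6974406 in the arm (2.04) and the next at 24019422 to 24022522 in the proximal window (1.78). The second clusters on 2L and 3R lay in the arms, at 2L 10219416 to 10242232 (22.8 kb, 1.89) and 3R 3010192 to 3013900 (1.89). On chromosome 4 the leading clusters were at the left end of the sequence, 2 to 5954 (combined score 1.76, with 1.16 and 2.30 in the replicates), and at 82702 to 91470 (1.74, 1.41 and 2.03). Of the 12 leading clusters on the arms and chromosome 4, 5 lay in a proximal window. The 2 on chromosome 4 could not, since proximal windows were defined on the arms only. Proximal windows held 3.85% of all combined clusters, a share not limited to clusters seen in both replicates as the 12 were.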

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

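The alternatives on the rest of the arms alone, on each class against its own shifted value, on scores within bins of cluster width, on the arms outside the proximal 2 Mb, on the scores of clusters found in both lists and on the extent of the pericentric blocks were chosen after the data were seen. Of 42 alternatives of results with a test, 41 kept their direction and stayed past the threshold of 0.05. The exception was the share of replicate 2 clusters overlapped on chromosome 4, 51.0% against 61.2% in shifted lists, and the cause was not tested. The 145 overlapped replicate 1 clusters there fell on 77 replicate 2 clusters, so this share does not by itself show poorer agreement. Counted among the 41 are the score differences in the higher-scoring 50% of each list, where the cut is made on the compared score itself. The share of replicate 1 clusters overlapped ranged from 51.0% to 99.7% and that of replicate 2 from 23.3% to 53.6%, the correlation of cover from 0.79 to 0.84 and that of scores from 0.71 to 0.79. With both lists cut by score to 4092 clusters, 68.7% of replicate 1 and 53.6% of replicate 2 clusters were overlapped. Shares and folds without a test moved more, and the cause was not tested unless the construction gives it. The higher-scoring 50% of each list has by construction a mean of 2777 clusters, and a cut by score keeps more of the classes with higher scores. It raised the share on the heterochromatin scaffolds to 24.4%, on unplaced sequence to 14.4% and in the proximal windows to 10.9%. The share of the rest of the arms fell to 47.2%. The same cut raised the cover over the rest of the arms to 11.7-fold for chromosome 4, 8.36-fold for the scaffolds, 9.43-fold for the proximal windows and 2.88-fold for unplaced sequence. In the higher-scoring 50% of the combined list 38.3% of clusters were seen in both replicates, 1.31% only in replicate 1 and 30.7% in neither. Requiring overlap of at least 50% of the combined cluster gave 13.7% in both, 35.1% only in replicate 2 and 47.3% in neither. Proximal windows of 2 Mb held 12.3% of clusters and left 62.7% in the rest of the arms, with a cover of 4.27-fold. Merging within 1 kb gave 12.3% for the scaffolds and 71.1% for the rest of the arms. By covered sequence the shares were 4.67% for chromosome 4, 19.6% for the scaffolds, 12.6% for the proximal windows and 56.0% for the rest of the arms. Leaving out a replicate gave 4092 to 7017 clusters and 10.0 to 21.6 Mb, and turned the fold of unplaced sequence from 2.08 without replicate 1 to 0.89 without replicate 2. No paired analysis was possible because the input libraries enter only through the authors' calls and have no values of their own here. The gene list alternatives were not run, since no annotation on release 5 was at hand. Depth is unknown, so how far it sets the length of each list could not be measured.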

Other observations

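Outside the pericentric regions some windows, among them windows on 2L, 2R and X, stood apart from the arms in both replicates. The windows named here are the 10 with the highest mean cover in that part of the arms, and were chosen after their values were seen. A mean cover over 25% was found in 17 windows, and those beyond the leading 10 are not listed. The number that passed the percentiles given below in both replicates was not counted. In the 1091 windows of 100 kb outside the proximal 2 Mb of the arms, the median cover was 3.58% in replicate 1 and 7.52% in replicate 2, with 95th percentiles of 13.7% and 25.5%. The leading window was 2L 10300001 to 10400000, covered to 33.3% and 68.6%, and its neighbour 10200001 to 10300000 was covered to 33.1% and 43.2%. The latter window holds the wide 2L cluster at 10219416 to 10242232. The window 2R 19900001 to 20000000 was covered to 29.3% and 61.2%. The windows 2R 19700001 to 19800000 (17.7% and 41.1%) and 2L 6900001 to 7000000 (18.4% and 35.6%) followed, and all these passed both percentiles. On the X the windows 15700001 to 15800000 (19.8% and 35.5%), 15800001 to 15900000 (17.0% and 44.8%) and 6100001 to 6200000 (17.0% and 37.5%) also passed both. The percentiles come from the same windows, so some windows pass them by construction. The windows X 19500001 to 19600000 (12.2% and 57.4%) and X 1900001 to 2000000 (12.6% and 45.2%) passed the percentile of replicate 2 only.

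The ends of the assembled arms away from the centromere did not stand clearly above their arm in both replicates. Sequence not joined to the assembled arms is left out, so enrichment at the telomeres themselves cannot be judged from these windows. The distal 100 kb was covered to 4.36% and 8.70% on 2L, where the arm outside its proximal window had 4.38% and 8.25%. It was covered to 3.33% and 10.5% on 3L (rest of the arm 5.36% and 9.69%) and to 1.33% and 0% on 2R (7.56% and 13.6%). On 3R it was covered to 8.31% and 8.92% (rest of the arm 4.60% and 8.03%), and on the X to 7.23% and 8.03% (4.204% and 11.5%), so these ends stood above their arm mainly or only in replicate 1. The widest combined cluster seen in both replicates was 76.1 kb, at 2R 1434350 to 1510496, and the widest on chromosome 4 was 48.8 kb, at 192728 to 241496.

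The explanations weighed here concern the lists of 1 group, so the design gives no biological contrast and no biological explanation was tested. All tests of explanations given here were chosen after the pattern was seen. In 4 further tests scores of the replicate lists were set against each other, on the X and on the difference between heterochromatin and arms, and they are not interpreted because the scale of the score is not stated. They were left out after their results were seen.

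The X held a larger share of the arm clusters in replicate 2. X clusters were 473 of 3125 arm clusters in replicate 1 (15.1%, 13.9 to 16.4%) and 1101 of 5161 in replicate 2 (21.3%, 20.2 to 22.5%), with intervals that cover counting of clusters only. A looser threshold in replicate 2 stays open. Shortening its list by score to the length of replicate 1 gave an X share of 28.2%. In the full replicate 2 list the 10th percentile of scores was 0.442 on the X and 0.362 to 0.390 on the autosomal arms. The medians were 0.626 on the X and 0.526 to 0.549 on the autosomal arms. A cut by score therefore keeps more of the X clusters and cannot decide this. Whether 1 common score limited the clusters cannot be told from these values. More female larvae in replicate 2 would lower the share on the Y scaffold, and the 4.37-fold higher share there (2 and 15 clusters) points the other way, but it does not exclude this, since clusters on XHet and U also rose, from 215 to 766. A lower yield of X reads in replicate 1 cannot be excluded, as the lists hold no read counts.

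The highest scores of the combined list were shared by several clusters. Its 50 highest-scoring clusters had only 9 distinct scores, 47 of the clusters had a score shared with another, 34 lay on unplaced sequence, which holds 9.38% of the list, and their median width was 1.01 kb. Taken as powers with base 2, 8 of the 9 scores (88.9%) were whole multiples of 1 constant within 0.03, between 8 and 18 times it, against 55.6% at the 95th percentile and 66.7% at most in 1000 sets of random scores. This is consistent with scores of thin regions being log2 ratios of a few reads over a common floor. Of these 50 clusters 44 were in neither replicate list and 0 in both, so a ranking by score alone would lead with regions that neither replicate shows.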
